A study of Saccharomyces cerevisiae with 17 samples.

How the data were processed

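Total RNA from *Saccharomyces cerevisiae* of the W303 background was depleted of ribosomal RNA and sequenced as strand-specific libraries made with the dUTP method, per the labels' protocols. The labels describe 17 libraries in 10 groups. The groups were wild type, the *ume6*, *isw2*, *rpd3* and *rrp6* single deletions, an *isw2 rpd3* double deletion, and strains that carried Chd1-Ume6 in the wild type, *ume6* or *rrp6* background. The last group was a *ume6* deletion with a catalytically inactive form of the fusion. Chd1-Ume6 is an engineered nucleosome remodeler in which Chd1, an enzyme that slides nucleosomes, is joined to the DNA-binding domain of Ume6. Ume6 is a repressor that binds the URS1 element upstream of early meiotic and some metabolic genes.

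The authors deposited gene-level abundances in 15 columns, and every column of sample values was used. The first table held 8 columns of log2 abundance deposited by the authors without a pseudocount, together with a yes or no entry for a motif in each gene. The motif was not named in the header. The workbook held 7 sheets, each headed as log2 FPKM per the file headers, FPKM being fragments scaled by transcript length and by the mapped fragments of a library. The sheet of the *ume6* deletion was deposited on a log10 scale in spite of its header. Its standard deviation was 0.311 times the mean of the other sheets, close to the 0.301 that a log10 scale gives. Read as log10, its FPKM values summed to 938206, and read as log2 to 20678.5, while the other sheets summed to between 889087 and 1216140. It was therefore read as log10. The submitters' processing notes name CASAVA, TopHat2, SAMtools, Cuffdiff and Cufflinks 2.2.1, with no roles. The genome build, the annotation and whether the counting used strand are not given in the sources used here, so reads of genes that overlap on opposite strands cannot be assigned to either of them.

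The 17 labelled libraries did not map to columns in all groups. Wild type was a single column, whose digits fit a mean of several libraries made by the authors. Among 734 genes checked, its FPKM in thousandths was whole in 14.85%, in 30.0% when multiplied by 2 and in 90.9% by 6. A plain mean of only the 2 labelled isolates would be whole when multiplied by 2. Which libraries were averaged is not given, and the fit treated the mean as a single library. *isw2* was a single column for 2 labelled isolates. It was whole in 100% of 719 genes without multiplying, so its digits gave no sign of averaging. The *ume6* deletion, Chd1-Ume6 in *ume6* and Chd1-Ume6 in wild type had a column in each table, whose isolate number is not given. They are called the library of the first table and the library of the workbook. The *rrp6* groups had 2 numbered columns each, both in the workbook. The *rpd3*, double deletion and inactive fusion groups had 1 column each. The labels number isolates but do not say that they were separate cultures, so p-values measure the spread between these columns, which may be technical. Values deposited as NA were treated as missing, a choice made after the files were examined, because *TDH3* and *ENO2*, among the most abundant yeast transcripts, were NA in the wild type column. Depth per library is unknown, since the columns hold no counts. The sums over genes of the FPKM values lay between 889087 and 1216140.

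Values were returned to FPKM and compared as log2(FPKM + 1), so a fold change understates the change of genes with low FPKM. Of 6644 genes in both tables, 6241 had a value in all 15 columns and an FPKM of at least 1 in at least 2 of them. limma 3.58.1 in R 4.3.3 was fitted once to all 15 columns with the 10 groups and a term for the deposited table, because the tables were normalized separately. The fit left 4 residual degrees of freedom. Every group shared 1 estimate of the spread per gene, moderated with a trend on abundance, and a group with 1 column was assumed to vary like the others. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Wild type was only in the first table and *rrp6* only in the workbook, so their comparison rests on the 3 groups that both tables share. The planned fit had assumed 17 libraries. With the 15 columns that the tables hold, *isw2*, *rpd3* and the double deletion were each 1 column against the wild type column of the same table. Their p-values rest entirely on the spread of the groups with 2 columns, so genes at least 2-fold apart are counted beside them.

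Gene lists were fixed from textbook knowledge before the data were examined. The lists were the engineered genes, early meiotic, URS1 metabolic, middle sporulation, a-specific, alpha-specific, pheromone response, ribosomal protein, ribosome biogenesis, stress, glucose-repressed and respiratory, phosphate, amino acid, auxotrophic marker and histone genes, with small nucleolar RNA and Ty genes. The last pair of lists had 0 members in the tables, and 3 of the 5 engineered genes were in the fit. Any call of the engineered list follows from how the strains were built, so these genes are given singly. The authors' motif genes, 227 of 237 in the fit, formed the remaining list. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry. Results of fry are given only for some lists, and a list that did not hold with an estimated correlation may pass with fry. Adjusted p-values of lists cover the 16 lists of a comparison. A list's median was also placed among 10000 random lists of the same size matched on abundance. The random lists were drawn from all tested genes, members of the list included. These percentiles are printed for some lists only. A call printed without one does not show that the list moved beyond genes of like abundance. The rule for named genes, fixed at the same time, took up to 10 genes per direction with the largest change among those that passed, with a mean FPKM of at least 5 and the same direction in each pair of columns within a table. It also took the engineered genes and up to 4 members of each list with the largest moderated t statistic. Open reading frames known only by a systematic name were left out of the choice by size of change. Genes of multicopy families, such as *PAU*, *COS*, *FLO*, *HXT* and *THI* genes, were left out of it too.

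The fit was tested on simulated data that held 200 changed genes of 6241 in each of 5 sets. At 4-fold it recovered 89.2% of the changed genes for the *ume6* deletion against wild type, 98.8% for Chd1-Ume6 in *ume6* and 73.6% for *rrp6* against wild type. At 2-fold these shares were 13.2%, 40.8% and 4%. For the 3 comparisons of 1 column against 1, the share at 4-fold ran from 78% to 82.8%. False calls made up 4.40% to 7.39% of all calls over the 12 comparisons. The simulated groups all had the same spread, so the assumption about groups with 1 column was not tested. Noise was drawn independently for each gene, without shifts shared by the genes of a library. The share of false calls therefore need not hold where genes of a column vary together.

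Alternatives were another pseudocount of 0.1 or 5, no filter on low values or a stricter filter, quantile normalization, centring on library medians, no term for the table, each table alone, a replicate block for the numbered *rrp6* isolates, and each replicated column left out in turn. Treating NA as 0, a block that crosses the isolate numbers of the *rrp6* groups, and the motif genes without the early meiotic genes among them, were added after the data were examined. The first table alone left 0 residual degrees of freedom and gave values without a test, and the workbook alone left 2. The block had been planned for all numbered isolates in place of the term for the table, but it was possible only between the *rrp6* groups and was added to that term. No group had 3 columns, so other splits of the samples were not counted. Without scaling, the median change over all genes was 0.14 on the log2 scale in *rrp6* against wild type and -0.06 after centring. In the *ume6* deletion it was 0.04, and -0.11 after centring. Positions of the URS1 core and neighbouring genes were taken from the reference genome R64, used only for sequence matches, names and neighbours, and 5992 of the 6644 identifiers matched its locus tags. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.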

Results

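RNA levels of 6241 genes were compared in 10 groups of yeast strains. Wild type, *isw2*, *rpd3*, the *isw2 rpd3* double deletion and *ume6* with the inactive fusion had 1 column each. The *ume6* deletion, Chd1-Ume6 in *ume6*, Chd1-Ume6 in wild type, *rrp6* and Chd1-Ume6 in *rrp6* had 2 columns each. Every comparison against wild type, and both interactions, used the same wild type column. A change that recurs among them, such as a fall of ribosomal protein genes, *BSC1* or *PRM7*, may therefore come from that column. Such a recurrence is not independent evidence. The series was designed to learn how repositioned nucleosomes affect transcription, and it includes a remodeler without catalytic activity as a control. Replicate columns correlated with r between 0.945 for Chd1-Ume6 in wild type and 0.974 for *ume6*, with 632 and 203 genes at least 2-fold apart. Depth is unknown because the values are FPKM, and the sum of FPKM per column ran from 889087 to 1216140. Changes are limma estimates on the log2(FPKM + 1) scale with their standard error (SE), and folds are those of FPKM + 1.

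The engineered genes showed the genotype in every column where the deleted gene had a value, and it was missing in 2 columns. *ISW2* was at 0.00613 FPKM in *isw2* and 0.0818 in the double deletion, against 28.0 in wild type. *RPD3* was at 0.0479 FPKM in *rpd3* and 0.110 in the double deletion, against 50.5 in wild type. *RRP6* was at 1.68 and 0.125 FPKM in the *rrp6* columns, and it was NA and 0.252 in *rrp6* with the fusion, against 77.1 in wild type. *UME6* was at 0.0536 FPKM in the *ume6* column of the first table and NA in that of the workbook, against 9.50 in wild type. The fusion contributes reads to both of its parent genes. *CHD1* was at 32.6 FPKM in wild type, 1608 with the inactive fusion, 836 and 1075 with Chd1-Ume6 in *ume6*, 505 and 449 in wild type with the fusion, and 288 and 276 in *rrp6* with the fusion. *UME6* was at 113 FPKM with the inactive fusion and at 65.5 and 73.4 with Chd1-Ume6 in *ume6*. *URA3* was at 81.8 FPKM in wild type and at 1213 with the inactive fusion, and it was between 216 and 761 in every column with the active fusion. In the columns without a fusion *URA3* was between 58.5 and 114 FPKM, so its calls mark strains with either form of the fusion. Whether its rise is a response to the fusion or follows from how the strains were built was not tested.

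Loss of Ume6 tests which genes the repressor holds down. *INO1*, which encodes inositol-3-phosphate synthase, rose 164-fold in *ume6* against wild type (7.36 ± 0.60 SE on the log2 scale, adjusted p = 0.000913, n = 2 against 1). *SAE3*, a meiotic strand-exchange factor, rose 69.4-fold (6.12 ± 0.32 SE, adjusted p = 7.38e-05), from 0.498 FPKM in wild type to 105.5 and 103.4 in the *ume6* columns. *HED1*, a meiotic gene, rose 47.6-fold (5.57 ± 0.28 SE, adjusted p = 7.38e-05). *DIP5*, an amino acid permease gene, fell by 2.72 on the log2 scale (SE 0.45, adjusted p = 0.0199). In all, 133 genes changed, with 99 higher and 34 lower. Of the 99, 39 carried the authors' motif entry, and none of the 34 did. Also among the largest rises were *RNP1* (5.47), *SRT1* (4.35), *OYE3* (4.35), *HOP2* (4.26), *HSP12* (4.21), *REC8* (4.14) and the acetyl-CoA synthetase gene *ACS1* (4.14), all of them with the motif except *OYE3* and *HSP12*. Under the rule for named genes, the largest falls after *DIP5* were those of *BSC1* (-2.66), *IRC7* (-2.22), *PRM7* (-2.10), *SRD1* (-2.09), *CIT2* (-2.07), *HO* (-1.94), *NCA3* (-1.87), *ENA1* (-1.87) and *LEU2* (-1.86).

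The 32 early meiotic genes had a median change of 2.68, and 23 of them rose, or 27 adjusted over the list alone (camera adjusted p = 1.68e-32, and adjusted p = 0.0133 with an estimated correlation). *IME2*, a meiotic kinase gene, rose by 3.45 and *MEI5* by 4.02. The authors' 227 motif genes had a median of 0.51 (camera adjusted p = 6.93e-11, and adjusted p = 0.0069 with an estimated correlation), with 39 risen, and adjusted over the list alone with 72 risen and 9 fallen. Of the 227, 21 are also early meiotic genes, and the 206 others had a median of 0.41 (camera adjusted p = 2.64e-06, and adjusted p = 0.0133 with an estimated correlation). For the lists that follow, the call with the preset did not hold with an estimated correlation, where the adjusted p lay between 0.197 and 0.743. The 12 URS1 metabolic genes had a median of 1.23 (6.49e-05), with 4 risen, among them *SIP4* (3.90) and the arginase gene *CAR1* (2.61). The 136 ribosomal protein genes had a median of -0.91 (1.82e-37), with 7 fallen, or 98 fallen and 1 risen adjusted over the list alone. The ribosome biogenesis genes had a median of -0.60 (5.37e-05), the stress genes 1.02 (0.00123), the phosphate genes -1.42 (1.27e-06), and the auxotrophic marker genes -0.81 (0.00211). With fry the URS1 metabolic (adjusted p = 0.0128), ribosomal protein (0.0175) and marker genes (0.0135) passed. The ribosome biogenesis, stress and phosphate genes did not pass with fry, where the lowest adjusted p was 0.199. Lists without a call at the preset were middle sporulation (-0.06), a-specific (-0.12), alpha-specific (0.06), pheromone response (-0.01), glucose-repressed and respiratory (0.29), amino acid (-0.13), histone (-0.23) and the engineered genes (-0.21). The count of changed genes was 23 without the *ume6* library of the first table and 54 without that of the workbook. It was 77 without either library of Chd1-Ume6 in *ume6*, 274 without *rrp6* library 1 and 269 without *rrp6* library 2. It was 76 after quantile normalization, 204 with no table term and 236 with the crossed replicate block. Without the *ume6* library of the first table the stress median was 0.33, no longer a call.

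**Figure D1:**
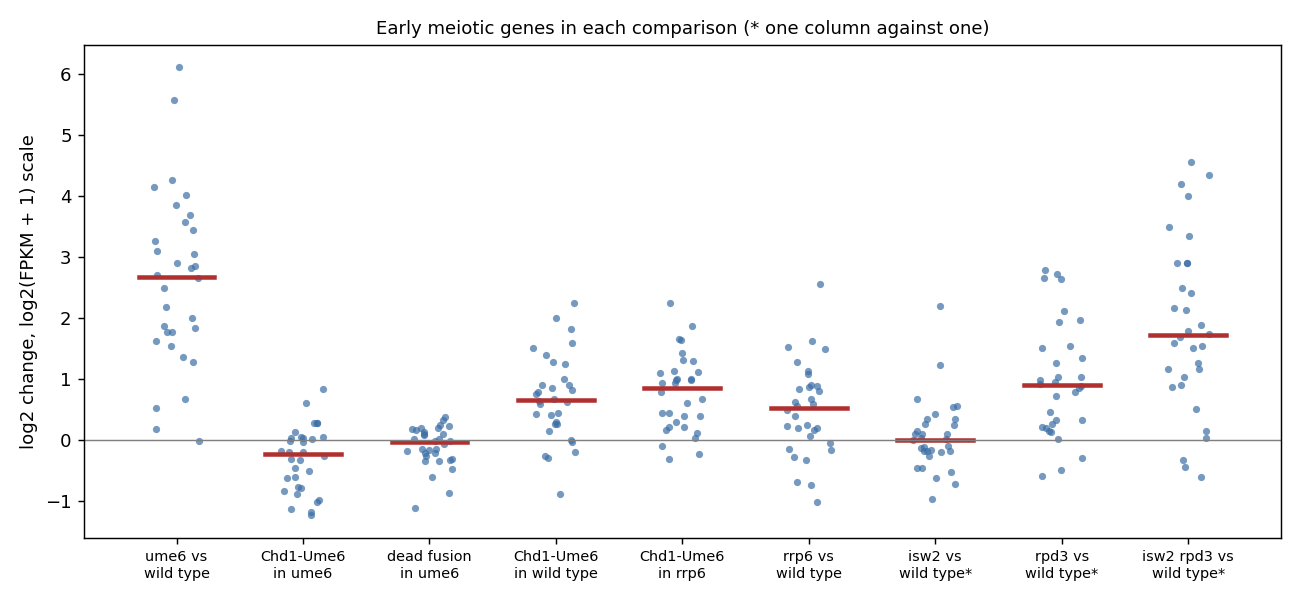
Change in RNA level of each of the 32 early meiotic genes (points, log2 scale of FPKM + 1, y axis) in each comparison (x axis), with the median as a red line and an asterisk at comparisons of 1 column against 1, whose test uses the spread of the other groups. The median is 2.68 in the *ume6* deletion, -0.23 with Chd1-Ume6 added to *ume6*, and 0.65 with Chd1-Ume6 added to wild type.

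Chd1-Ume6 in the *ume6* deletion tests whether a remodeler brought to URS1 sites can take over from the missing repressor. *IME2* was at 70.7 and 76.7 FPKM in *ume6* and at 35.3 and 30.8 with the fusion, a change of -1.13 ± 0.20 SE that did not pass over all genes (adjusted p = 0.0765, n = 2 against 2). *HED1* changed by -1.02 ± 0.21 SE (adjusted p = 0.0827) and *SAE3* by -0.89 ± 0.24 SE (adjusted p = 0.191). *HOP1*, a meiotic chromosome gene, went the other way, from 60.3 and 43.6 FPKM to 86.6 and 98.5 (0.84 ± 0.27 SE, adjusted p = 0.305). The 32 early meiotic genes had a median of -0.23 (camera adjusted p = 6.4e-06, and adjusted p = 0.324 with an estimated correlation), with 21 of them lower. With fry the adjusted p of this list was 0.104. *IME2*, *HED1*, *SAE3*, *SLZ1* (-1.24), *SPO13* and *RIM4* (-0.84) fell adjusted over the list alone. The 227 motif genes had a median of -0.04 (camera adjusted p = 0.000167, and adjusted p = 0.0492 with an estimated correlation), and 8 of them fell adjusted over the list alone. Without the 21 early meiotic genes among them the median was -0.03, and the call did not hold with an estimated correlation (adjusted p = 0.0735). *INO1* was at 2390 and 3476 FPKM in *ume6* and at 947.6 and 826.6 with the fusion (-1.70 ± 0.47 SE, adjusted p = 0.191), and in wild type it was at 14.9 FPKM. *CAR1* changed by -1.43 ± 0.33 SE (adjusted p = 0.111).

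In that comparison 14 genes changed, with 13 higher and 1 lower, none of them a motif gene. *CHD1* rose by 5.12 ± 0.23 SE (adjusted p = 6.11e-05, n = 2 against 2) and *URA3* by 2.53 ± 0.22 SE (adjusted p = 0.00689). *GRE2*, a methylglyoxal reductase gene, rose 7.12-fold (2.83 ± 0.38 SE, adjusted p = 0.0403), from 191.7 and 66.1 FPKM to 795.8 and 821.5. The multidrug transporter gene *FLR1* rose by 1.83, the nitroreductase-like genes *FRM2* and *HBN1* by 2.47 and 1.68, and the peroxidase gene *DOT5* by 1.32. *SDL1* rose by 2.44, *CFD1* by 1.72 and *RSM25* by 1.36. The 12 URS1 metabolic genes had a median of -0.70 (camera adjusted p = 0.000589), the phosphate genes -0.78 (2.44e-07), the amino acid genes -0.52 (6.05e-08) and the ribosomal protein genes -0.18 (1.32e-07). None of these 4 held with an estimated correlation, where the adjusted p was 0.332 for the first 3 of them and 0.688 for the ribosomal protein genes. The count of 14 was 3 and 1 without the *ume6* libraries of the first table and the workbook, 6 and 1 without those of Chd1-Ume6 in *ume6*, and 3 without any single library of Chd1-Ume6 in wild type or in *rrp6*. Without the workbook library of Chd1-Ume6 in *ume6* the ribosomal protein median was -0.02, no longer a call. The count was 4 with the replicate block, 8 with the crossed replicate block, 7 after quantile normalization and 23 with a pseudocount of 5.

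**Figure D2:**
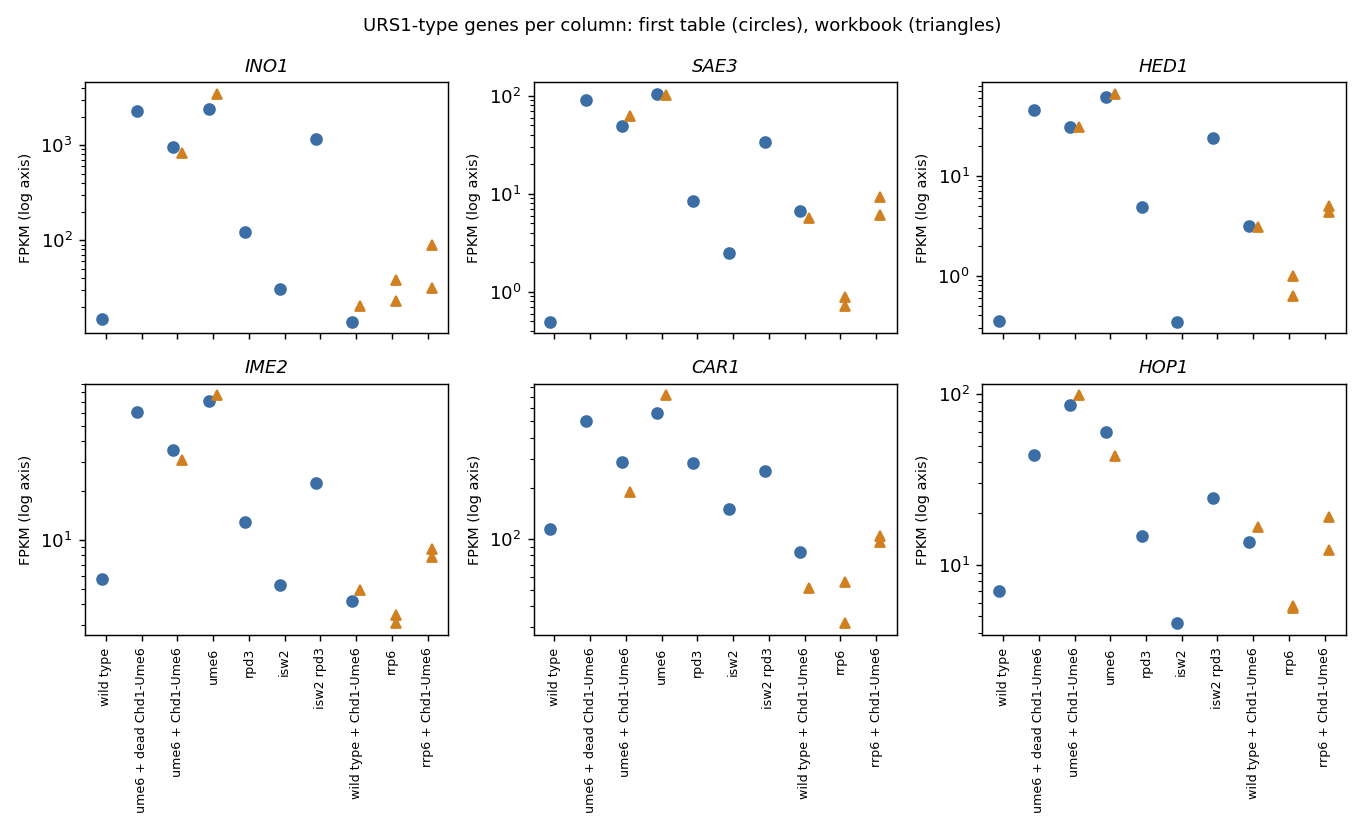
RNA level (FPKM, log y axis) of *INO1*, *SAE3*, *HED1*, *IME2*, *CAR1* and *HOP1* in the 10 groups (x axis), with a circle per column of the first table and a triangle per column of the workbook. *INO1* sits at 2390 and 3476 FPKM in *ume6* and at 947.6 and 826.6 with Chd1-Ume6, while *HOP1* sits higher with Chd1-Ume6 than in *ume6*.

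Genes were also chosen and measured on separate columns, so that no shared *ume6* library could produce a fall. A total of 602 genes were at least 2-fold higher in *ume6* than in wild type in the first table. In the workbook their median change with Chd1-Ume6 was 0.09, against 0.10 for all genes, with 260 of the 602 lower, and it lay at percentile 24.45 of random lists. This measure was set before the data were examined, and its outcome was not stable. With a pseudocount of 5, which alters both the genes chosen and the scale of the change, 417 genes had a median of 0.02 against 0.09 for all genes, at percentile 0.14. With the choice at 4-fold, 111 genes had a median of -0.13, at percentile 0. A split of the 602 chosen after the data were examined gave a median of -0.48 for the 80 motif genes, 57 of them lower, and 0.15 for the other 522, 203 of them lower.

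The inactive fusion in *ume6* is the control without catalysis, and it is 1 column. *INO1* was at 2286 FPKM with the inactive fusion, and *SAE3* at 91.8, *HED1* at 45.1 and *IME2* at 60.5 FPKM, and none of these 4 differed from *ume6* past the threshold. For the early meiotic genes the median was -0.04 (camera adjusted p = 0.6, and adjusted p = 0.891 with an estimated correlation), and the motif median was -0.13 (camera adjusted p = 0.114). With limma, 3 genes changed, which were *CHD1* (5.84 ± 0.29 SE, adjusted p = 0.000169, n = 1 against 2), *URA3* (3.56 ± 0.29 SE, adjusted p = 0.00354) and YOL085C, named after its value was seen. The acid phosphatase genes *PHO5* (2.68), *PHO12* (3.70) and *PHO11* (3.38) did not pass over all genes. The phosphate list had a median of 1.00 (camera adjusted p = 3.55e-08), and 3 of its genes rose adjusted over the list alone. The ribosomal protein genes had a median of 0.37 (6.1e-20), ribosome biogenesis 0.62 (7.44e-10), amino acid 0.36 (2.21e-05), glucose-repressed and respiratory -0.47 (0.00664) and a-specific genes 0.57 (0.018). These 6 calls did not hold with an estimated correlation, where the lowest adjusted p was 0.348. The a-specific call ended without the workbook *ume6* library or either library of Chd1-Ume6 in wild type, and the glucose-repressed and respiratory call without the first-table *ume6* library. The count was 1 without the *ume6* library of the first table and 5 without *rrp6* library 2.

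Between active Chd1-Ume6 and the inactive fusion in *ume6*, 22 genes differed, with 20 higher and 2 lower. The inactive fusion has no spread of its own, so features of that library cannot be separated from an effect of catalysis. One such feature is the RNA level of the fusion, with *CHD1* at 1608 FPKM with the inactive fusion and at 836 and 1075 with the active one. *GRE2* was 21.7-fold higher (4.44 ± 0.49 SE, adjusted p = 0.0141, n = 2 against 1) and *FLR1* 11.4-fold higher (3.51 ± 0.34 SE, adjusted p = 0.00702). *PHO5* was 27.3-fold lower (-4.77 ± 0.60 SE, adjusted p = 0.0219), at 28.8 and 23.2 FPKM against 714 with the inactive fusion and 122 and 105 in *ume6*. *BAT1*, which encodes a branched-chain aminotransferase, was the other lower gene (-1.87 ± 0.26 SE, adjusted p = 0.031). Higher genes included *FRM2* (3.57), the glutathione transferase genes *GTT2* (3.40) and *ECM4* (2.97), *HBN1* (3.08), the peroxidase gene *AHP1* (2.93), *SDL1* (2.81), *YKE4* (2.15) and *FMC1* (1.93). None of the URS1 genes passed over all genes, with *IME2* at -0.87 (adjusted p = 0.194), *SLZ1* at -1.47 (adjusted p = 0.131) and *HOP1* at 1.05 (adjusted p = 0.234). The early meiotic median was -0.29 (camera adjusted p = 0.00647, and adjusted p = 0.357 with an estimated correlation). The phosphate genes had a median of -2.03 (2.05e-13), and 9 of the 12 fell adjusted over the list alone. The amino acid genes had a median of -0.88 (1.59e-12), ribosomal protein genes -0.56 (5.46e-28) and ribosome biogenesis genes -0.48 (3.01e-07), none of which held with an estimated correlation. The URS1 metabolic median was -0.21 (0.19) and the motif median 0.00 (0.227). The count of 22 was 4 and 5 without the libraries of Chd1-Ume6 in *ume6* of the first table and the workbook, 10 without either *ume6* library, 35 without either *rrp6* library, and 9 and 11 without library 1 and 2 of Chd1-Ume6 in *rrp6*. It was 14 after quantile normalization and 45 with no table term. Without the first-table library of Chd1-Ume6 in *ume6* the early meiotic median was -0.06, no longer a call (adjusted p = 0.139).

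Chd1-Ume6 in wild type tests the fusion beside the native repressor. *CHD1* rose 14.6-fold (3.87 ± 0.29 SE, adjusted p = 0.00465, n = 2 against 1) and was the only gene of 6241 that limma called, with 537 genes at an unadjusted p under 0.05. *SAE3* was at 6.66 and 5.72 FPKM with the fusion and 0.498 without it (2.24 ± 0.32 SE, adjusted p = 0.105). *MEI5* changed by 1.99 ± 0.33 SE (adjusted p = 0.15), *ECM11* by 1.81 ± 0.35 SE (adjusted p = 0.277) and *HED1* by 1.59 ± 0.28 SE (adjusted p = 0.216). *IME2* changed by -0.30. The early meiotic genes had a median of 0.65, with 27 of 32 higher and 9 risen adjusted over the list alone (camera adjusted p = 2.77e-09, and adjusted p = 0.279 with an estimated correlation). With fry the adjusted p of this list was 0.0226. The motif genes had a median of 0.08 (camera adjusted p = 0.337), with 8 risen adjusted over the list alone. The 12 URS1 metabolic genes had a median of -0.19 (0.243), with 7 of them lower. Amino acid genes had a median of -0.34 (5.21e-06), a-specific genes 0.45 (0.0351), ribosomal protein genes -0.43 (3.03e-19) and histone genes -0.22 (0.0351). After quantile normalization the last 2 were 0.05 and 0.18. The histone median was 0.00 without the first-table library of Chd1-Ume6 in wild type, and none of these 4 calls held with an estimated correlation. The ribosomal protein median lay at percentile 55.97 of random lists, so the list is not shown to have fallen beyond genes of like abundance. The random lists could hold ribosomal protein genes themselves, so this percentile does not show how far other genes fell. Amino acid genes lay at percentile 1.48 and a-specific genes at 99.71. The count of changed genes was 0 without the first-table library of Chd1-Ume6 in wild type 2 without any single library of *rrp6* or of Chd1-Ume6 in *rrp6*, 2 with no table term, 3 with the crossed replicate block or with missing values as 0, and 7 with a pseudocount of 0.1. The a-specific call ended without either *ume6* library or the workbook library of Chd1-Ume6 in wild type.

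Whether the fusion acts differently in the presence of native Ume6 was tested as an interaction between the *ume6* and wild type backgrounds. The level of the fusion differed between them, with *CHD1* at 836 and 1075 FPKM in *ume6* and at 505 and 449 in wild type. This difference was not separated from the background. *SAE3* differed by -3.13 ± 0.40 SE (adjusted p = 0.0724, n = 4 against 3) and *HED1* by -2.61 ± 0.35 SE (adjusted p = 0.0737). No single gene passed, as limma called 0 genes, with 395 at an unadjusted p under 0.05. The count was 4 with a pseudocount of 0.1, with no table term or with missing values as 0, and 2 without the first-table library of Chd1-Ume6 in *ume6*. The early meiotic median of the difference was -0.88 (camera adjusted p = 2.83e-18, and adjusted p = 0.0392 with an estimated correlation), with 13 genes fallen adjusted over the list alone. The motif genes had a median of -0.16 (camera adjusted p = 0.000435, and adjusted p = 0.0392 with an estimated correlation). Without the 21 early meiotic genes among them it was -0.11 (camera adjusted p = 0.0487), which did not hold with an estimated correlation (adjusted p = 0.0987). Middle sporulation genes had a median of 0.37 (0.0324) and ribosomal protein genes 0.24 (3.64e-05), which was -0.24 after quantile normalization, and neither held with an estimated correlation. Both of these calls also ended without the first-table *ume6* library, at adjusted p = 0.0996.

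Rrp6 is a nuclear exosome subunit that degrades noncoding and extended transcripts, and its deletion tests whether such RNA hides the effect of the fusion. *SAE3* rose 4.76-fold with Chd1-Ume6 in *rrp6* (2.25 ± 0.24 SE, adjusted p = 0.0169, n = 2 against 2), from 0.890 and 0.714 FPKM to 6.17 and 9.23. *HED1* rose by 1.65 (adjusted p = 0.0233) and *MEI5* by 1.64 (adjusted p = 0.0351), while *IME2* at 1.12 did not pass (adjusted p = 0.053). *HSP12*, a stress gene, rose 13-fold (3.70 ± 0.57 SE, adjusted p = 0.0351). *HEM13*, a heme biosynthesis gene, fell by 2.42 (SE 0.32, adjusted p = 0.0233). In all, 44 genes changed, with 38 higher, 7 of them motif genes, and 6 lower. *CHD1* (3.13), *NCE103* (2.91), the heme oxygenase gene *HMX1* (2.84), *SPG4* (2.48), *PYC1* (2.04), *PRM10* (1.96), *URA3* (1.88) and *SRY1* (1.79) also rose, and *MRH1* (-1.86), *PMP2* (-1.37), *LAC1* (-1.37) and *FAA4* (-1.33) fell.

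The early meiotic genes had a median of 0.86 with Chd1-Ume6 in *rrp6*, with 29 of 32 higher, 3 risen, and 17 risen adjusted over the list alone (camera adjusted p = 1.76e-10, and adjusted p = 0.119 with an estimated correlation). The motif genes had a median of 0.13 (0.0167), which ended as a call without the early meiotic genes among them (0.18), URS1 metabolic genes 0.88 (8.85e-05) and alpha-specific genes 0.82 (0.0203). Stress genes had a median of 0.79 (1.47e-05), glucose-repressed and respiratory genes 0.90 (1.17e-07) and phosphate genes 0.67 (0.00347). Ribosomal protein genes had a median of -0.26 (1.14e-12), ribosome biogenesis genes -0.34 (3.69e-05) and histone genes -0.40 (8.37e-05). No list in this comparison held with an estimated correlation, where the lowest adjusted p was 0.119. The count of 44 was 107 and 5 without *rrp6* libraries 1 and 2, 54 and 0 without libraries 1 and 2 of Chd1-Ume6 in *rrp6*, 4 without either *ume6* library, 5 without either library of Chd1-Ume6 in *ume6*, and 10 without either library of Chd1-Ume6 in wild type. It was 9 after quantile normalization, 11 after centring, 29 with the replicate block and 150 with the crossed replicate block. Without *rrp6* library 2 the calls of the motif and alpha-specific genes ended, and the phosphate median was 0.02 and the ribosome biogenesis median 0.00. Without library 2 of Chd1-Ume6 in *rrp6* the motif call ended, and the stress median was 0.20 and the ribosome biogenesis median 0.05. Without library 1 of it the alpha-specific and phosphate calls ended, at adjusted p = 0.156 and 0.0603, and after quantile normalization those of the ribosomal protein and alpha-specific genes did.

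The interaction of the fusion with the *rrp6* background called 2 genes. The level of the fusion was not separated from the background, with *CHD1* at 288 and 276 FPKM in *rrp6* and at 505 and 449 in wild type. *NCE103*, a carbonic anhydrase gene, differed by 4.97 ± 0.52 SE (adjusted p = 0.0302, n = 4 against 3). With the fusion it was at 642 and 547 FPKM in *rrp6* and at 88.0 and 173 in wild type, and without it at 92.4 and 65.3 in *rrp6* and at 284 in wild type. *PCA1*, a cadmium transporter gene, differed by 3.38 ± 0.35 SE (adjusted p = 0.0302). For the early meiotic genes the median difference was 0.03 (camera adjusted p = 0.92). URS1 metabolic genes had a median of 1.18 (0.000776), glucose-repressed and respiratory genes 0.89 (9.39e-07), phosphate genes 1.07 (0.000803) and amino acid genes 0.43 (0.000803). All 7 a-specific genes were lower, with a median of -0.44 (0.00623), and all 4 alpha-specific genes higher, with 1.12 (0.00884). Stress genes had a median of 0.82 (0.00873), ribosome biogenesis genes -0.38 (0.00873) and middle sporulation genes 0.50 (0.0309). None of these 9 calls held with an estimated correlation, where the lowest adjusted p was 0.406. The stress and ribosome biogenesis calls ended without *rrp6* library 2, at adjusted p = 0.131 and 0.393, and without library 2 of Chd1-Ume6 in *rrp6* (0.595). Without the first-table library of Chd1-Ume6 in wild type (0.237) both ended as well, with a stress median of -0.16. The alpha-specific call ended without library 1 of Chd1-Ume6 in *rrp6* (0.0724). The middle sporulation call ended without the workbook library of Chd1-Ume6 in wild type (0.126) or any single library of Chd1-Ume6 in *ume6*, of *rrp6* or of Chd1-Ume6 in *rrp6*, where the lowest adjusted p was 0.0517. Both gene calls ended after quantile normalization, at adjusted p = 0.0688. The count was 46 with the crossed replicate block and 5 with missing values as 0. It was 0 without any single library of *ume6* or of Chd1-Ume6 in *ume6*, 3 and 0 without those of Chd1-Ume6 in wild type, 47 and 1 without *rrp6* libraries 1 and 2, and 17 and 0 without those of Chd1-Ume6 in *rrp6*.

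Deletion of *RRP6* alone was compared with wild type across the tables. *CMC4* rose 79-fold (6.30 ± 0.43 SE, adjusted p = 0.000895, n = 2 against 1), from 35.4 FPKM in wild type to 3065 and 4616. *LIN1* rose 29.7-fold (4.89 ± 0.45 SE, adjusted p = 0.00476) and *GLO4* 16-fold (SE 0.35 on the log2 scale, adjusted p = 0.00476). *CIT2*, a citrate synthase gene, fell by 3.18 (SE 0.34, adjusted p = 0.0108). In all, 27 genes changed, with 20 higher and 7 lower. *MMS2* (2.95), *CUE5* (2.77), the meiotic recombination gene *MEI4* (2.55), *OAR1* (2.43), *HAP5* (2.30), *RPR2* (2.28) and *ATG14* also rose. *MET17* (-3.64), *NCE103* (-3.58), *BSC1* (-3.09), *PRM7* (-2.71) and *NDE1* (-1.96) fell. Estimates in this comparison include the term for the table, so they can differ from the FPKM of the columns. For *NCE103* the estimate is an 11.9-fold fall, and the FPKM values given for it above show a smaller one. The early meiotic genes had a median of 0.51 (camera adjusted p = 0.00735, and adjusted p = 0.473 with an estimated correlation), which ended as a call after quantile normalization, at 0.12 (adjusted p = 0.340). Phosphate genes had a median of -1.74 (2.15e-10), amino acid genes -0.50 (1.18e-08), glucose-repressed and respiratory genes -0.86 (3.33e-07), middle sporulation genes 0.71 (0.0153), stress genes -0.38 (0.0181), and ribosomal protein genes -0.40 (2.9e-16), which was 0.09 after quantile normalization. None of these held with an estimated correlation. The count of 27 was 53 and 16 without *rrp6* libraries 1 and 2, 8 without any single library of *ume6* or of Chd1-Ume6 in *ume6*, and 12 without either library of Chd1-Ume6 in wild type. It was 8 with the replicate block, 43 with a pseudocount of 5 and 59 with no table term, and the stress median was 0.11 without either library of Chd1-Ume6 in wild type. The calls of the early meiotic and middle sporulation genes ended without *rrp6* library 1, that of the stress genes without *rrp6* library 2, and that of the middle sporulation genes without either library of Chd1-Ume6 in wild type.

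**Figure D3:**
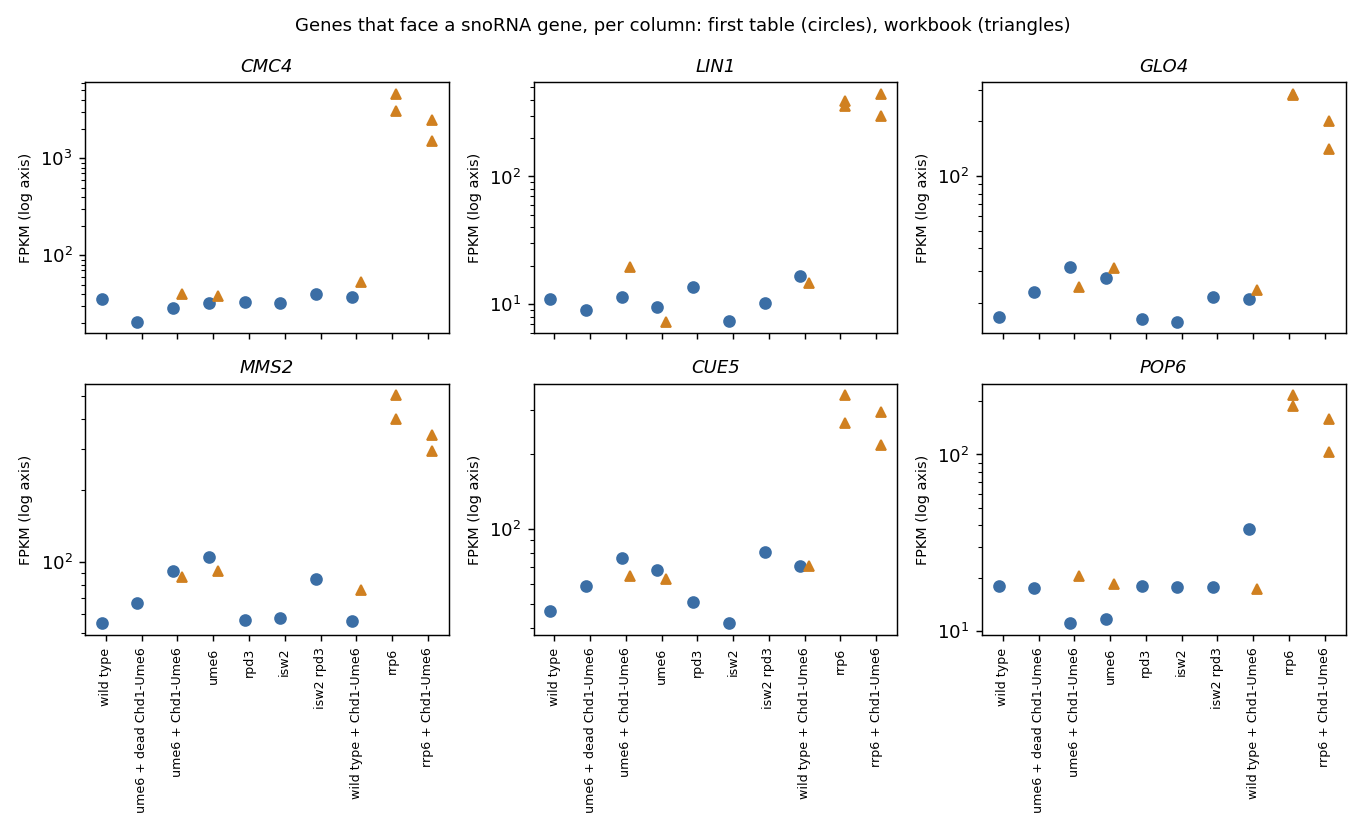
RNA level (FPKM, log y axis) of *CMC4*, *LIN1*, *GLO4*, *MMS2*, *CUE5* and *POP6* in the 10 groups (x axis), with a circle per column of the first table and a triangle per column of the workbook. *CMC4* lies between 1519 and 4616 FPKM in the 4 columns of *rrp6* strains and between 20.8 and 53.6 in the 11 others.

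The remaining deletions address Isw2, a remodeler, and Rpd3, a histone deacetylase, both of which Ume6 brings to its targets. Each is 1 column against the wild type column, so the spread behind its test comes from other groups, and features of that library cannot be separated from the genotype. In *isw2*, limma called 1 gene of 6241, *ISW2* itself, which fell by 4.85 (SE 0.43, adjusted p = 0.0153, n = 1 against 1), with 82 genes at an unadjusted p under 0.05. *HOP2* was at 7.60 FPKM against 0.879 in wild type (2.19 ± 0.40 SE, adjusted p = 0.486), and *SAE3* at 1.22 ± 0.35 SE did not pass either. Whatever their p-value, 46 genes were at least 2-fold higher and 28 lower. The 82 genes are fewer than the share of 0.05 that p-values without any effect would give among 6241. The borrowed spread may therefore be too wide for these columns, and a single call does not show that the deletion has little effect. Early meiotic genes had a median of 0.00 (camera adjusted p = 0.486, and adjusted p = 0.865 with an estimated correlation). The URS1 metabolic median was 0.12 (0.463), at percentile 99.28 of random lists, and the motif median -0.09 (0.463), at percentile 0.12. The ribosomal protein genes had a median of -0.19 (1.7e-06), which did not hold with an estimated correlation and was 0.0067 after quantile normalization. The call of *ISW2* ended without either *ume6* library, at adjusted p = 0.0674 and 0.0665, with no table term, at 0.1002, and with the replicate block (0.0693). The count was 2 with a pseudocount of 5, where *ISW2* did not pass, and 2 with missing values as 0.

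In *rpd3*, *SAE3* rose 6.29-fold against wild type (2.65 ± 0.35 SE, adjusted p = 0.013, n = 1 against 1), from 0.498 to 8.42 FPKM. *ECM11* rose 6.22-fold (adjusted p = 0.0222), *MND1* 6.87-fold (adjusted p = 0.0444) and *HED1* 4.34-fold (adjusted p = 0.0206), while *INO1* at 2.94 ± 0.66 SE did not pass (adjusted p = 0.103). *SHC1* (3.22), *GLG2* (2.33), *SRT1* (1.89), *FMT1* (1.86), *PEX30* (1.82) and *ECM29* (1.74) also rose. *RPD3* fell by 5.62 (SE 0.26, adjusted p = 8.99e-05). The NAD synthesis genes *BNA1* (-4.43), *BNA2* (-4.04) and *BNA5* (-2.85), the nicotinic acid transporter gene *TNA1* (-3.18), *DAL80* (-3.53), *PYK2* (-3.31), *DAL4* (-2.80), *SMP1* (-2.74) and *DAL1* (-2.49) also fell. In all, 55 genes changed, with 17 higher, 5 of them motif genes, and 38 lower, 4 of them motif genes. Whatever their p-value, 238 genes were at least 2-fold higher and 335 lower.

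The early meiotic genes in *rpd3* had a median of 0.89, with 5 risen, or 13 adjusted over the list alone (camera adjusted p = 6.25e-15, and adjusted p = 0.0569 with an estimated correlation). The motif median was 0.15 (0.00119), or 0.06 (0.0377) without the early meiotic genes among them, and the URS1 metabolic median 1.04 (0.000114). Middle sporulation genes had a median of -1.08 (3.78e-11), with 1 fallen, or 8 adjusted over the list alone. Histone genes had a median of -0.80 (6.94e-05), pheromone response genes -0.55 (0.00218) and ribosome biogenesis genes -0.35 (0.0351). Phosphate genes had a median of -0.58 without a call (0.0537), with 11 of 12 lower. No list in this comparison held with an estimated correlation, where the lowest adjusted p was 0.0569. The count of 55 was 28 without either *ume6* library and 29 without either library of Chd1-Ume6 in *ume6*, and the call of *HED1* ended without any of these 4, where its lowest adjusted p was 0.0599. It was 25 after quantile normalization, 18 and 90 with a pseudocount of 5 and 0.1, and 89 with the crossed replicate block. With a pseudocount of 5 the call of *SAE3* ended as well, at adjusted p = 0.111.

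In the *isw2 rpd3* double deletion, which was made in a prototrophic background, *INO1* rose 73.3-fold against wild type (6.20 ± 0.66 SE, adjusted p = 0.00348, n = 1 against 1). *SAE3* rose 23.5-fold (4.56 ± 0.35 SE, adjusted p = 0.000651), *SHC1* 27.6-fold, *RNP1* 21.2-fold, *HOP2* 20.4-fold, *HED1* 18.4-fold, *MND1* 16-fold, *ECM11* 11.3-fold and *SRT1* 11.1-fold. *RPD3* (-5.54), *BSC1* (-5.24), *ISW2* (-4.74), *PRM7* (-4.70), the a-factor gene *MFA1* (-4.14, adjusted p = 0.0212), *DIP5* (-4.03), *LEU1* (-3.77), *BNA1* (-3.60), *BNA2* (-3.52) and *OAC1* (-3.25) fell. In all, 237 genes changed, with 110 higher, 25 of them motif genes, and 127 lower, 1 of them a motif gene. Whatever their p-value, 434 genes were at least 2-fold higher and 516 lower. The background also differed at marker genes, as *HIS3* was at 569 FPKM against 35.7 in wild type, *ADE2* at 113 against 45.3 and *LEU2* at 67.6 against 227, with 2 of the 6 marker genes at least 2-fold higher and 2 lower. Effects of this background on the 237 genes and on the lists cannot be separated from those of the deletions.

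For early meiotic genes the median in the double deletion was 1.71, with 16 risen, or 25 adjusted over the list alone (camera adjusted p = 2.27e-18, and adjusted p = 0.0681 with an estimated correlation). The motif median was 0.20 (0.00402), which ended as a call without the early meiotic genes among them (0.142), and the URS1 metabolic median 1.01 (0.000645), with 4 of 12 risen. Middle sporulation genes had a median of -0.86 (1.13e-06), with 5 fallen, among them *NDT80* (-2.38), and a-specific genes -1.11 (0.00038), with 3 fallen. Ribosomal protein genes had a median of -0.43 (2.65e-10), glucose-repressed and respiratory genes -0.71 (0.000645), histone genes -0.59 (0.00402), pheromone response genes -0.42 (0.0183) and amino acid genes -0.31 (0.0219). None of these held with an estimated correlation, where the lowest adjusted p was 0.0681. After quantile normalization the ribosomal protein median was 0.06, and the calls of the histone, pheromone response and amino acid genes ended. The count of 237 was 123 without either *ume6* library, 128 without either library of Chd1-Ume6 in *ume6*, 108 after quantile normalization and 140 with the replicate block.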

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

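The tests of a low starting level, of growth state and of the separate normalization of the tables were chosen only after the result was seen, while the interaction between backgrounds was planned. Among the results, 2 overlapping lists and 2 genes responded differently to Chd1-Ume6 in different backgrounds by a test of the difference itself.

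Early meiotic genes responded differently in *ume6* and in wild type. The median difference was -0.88 (camera adjusted p = 2.83e-18, and adjusted p = 0.0392 with an estimated correlation). The median was -0.23 in *ume6*, where 11 of 32 genes were higher, and 0.65 in wild type. By itself neither held with an estimated correlation (adjusted p = 0.324 and 0.279). With fry the rise in wild type passed (adjusted p = 0.0226) and the fall in *ume6* did not (adjusted p = 0.104). None of these genes passed over all genes in either background, so a change of sign is not shown. The authors' motif genes differed by a median of -0.16 (camera adjusted p = 0.000435, and adjusted p = 0.0392 with an estimated correlation). They include 21 of the early meiotic genes, and the 206 others had -0.11 (camera adjusted p = 0.0487), which did not hold with an estimated correlation (adjusted p = 0.0987), so the motif list is not a separate result. The early meiotic difference ran from -0.70 with a pseudocount of 5 to -1.10 with a pseudocount of 0.1, and it passed at the preset in every alternative that could be tested. The camera test with an estimated correlation (adjusted p = 0.0392) was not repeated in the alternatives. How far that call depends on the processing or on single libraries is therefore unknown. *SAE3* shows the pattern, with 105.5 and 103.4 FPKM in *ume6* becoming 49.5 and 62.8 with the fusion, and 0.498 FPKM in wild type becoming 6.66 and 5.72.

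A low level in wild type, which leaves room only to rise, was tested with random lists matched on wild type FPKM. The early meiotic median of 0.65 lay at percentile 100 of 10000 such lists, whose median was 0.17 and whose upper bound was 0.34, which argues against a low level as the whole cause. Separate normalization of the tables would lose the difference within a single table, but within the first table it was -1.01, against a spread of the list between replicates of 0.135. A change of growth state stays open, because the stress list differed by -0.11 with a spread between replicates of 0.978, which is too wide to decide. A candidate explanation is that the fusion competes with native Ume6 at the same sites and lifts part of its repression. The URS1 metabolic genes do not decide it, with a median of -0.19 and no call in wild type with the fusion (camera adjusted p = 0.243), and 0.88 in *rrp6* with the fusion, a call that did not hold with an estimated correlation. Ume6 binding was not measured here, and this explanation was not tested. The RNA level of the fusion was also higher in *ume6* than in wild type, and this difference was not separated from the background.

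The other background difference was at *NCE103* (4.97) and *PCA1* (3.38), whose change with the fusion differed between *rrp6* and wild type (adjusted p = 0.0302 for both). *PCA1* went from 78.0 FPKM to 19.8 and 15.1 with the fusion in wild type, and from 28.8 and 31.4 to 71.3 and 89.6 in *rrp6*. The size of both differences barely moved after quantile normalization, at 4.96 and 3.34, while the adjusted p became 0.0688. Both calls ended without any single library of *ume6* (adjusted p = 0.0940 and 0.0934) or of Chd1-Ume6 in *ume6* (0.103), without *rrp6* library 2 (0.0613), without library 2 of Chd1-Ume6 in *rrp6* (0.0856) and without the workbook library of Chd1-Ume6 in wild type (0.0613 and 0.182). Without the first-table library of that group the call of *PCA1* ended (0.131), and with no table term that of *NCE103* did (0.306). Wild type has 1 column and *rrp6* lies in the other table, so the difference rests on the groups that both tables share. For these genes no technical or biological explanation was tested.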

How the results depend on the processing

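Missing values as 0, the crossed replicate block and the motif genes without the early meiotic genes were chosen after the data were examined, and all other alternatives before. Of 242 alternative counts of changed genes, 138 stayed within 1.5 times the count reported, 34 were larger and 70 smaller. For tested medians and genes, the same means only that the call at the threshold did not change, whatever the size of the change. Where neither value passed, a change of sign also counted as the same. Calls of lists in the alternatives are those of camera at the preset. Only medians without a test were compared by size and could be labelled moved. Of 210 alternative early meiotic medians, 207 were the same, 8 of them values of the first table alone without a test, 3 fell short of the threshold and 0 of those that passed reversed. Medians near 0 that never passed did cross 0, running from -0.13 to 0.060 with the inactive fusion and from -0.0089 to 0.019 in *isw2*. Of 3818 medians of the other lists, and of the early meiotic genes in the interactions, 3649 were the same, 129 of them without a test, 82 became calls, 60 ceased to be calls, 6 moved and 21 reversed. Of 16054 values of named genes, 15164 kept their call or lack of one, 136 became calls and 754 ceased to be calls. None that passed, in either fit, reversed in sign, and their size was not compared. Where no cause is given, the cause was not tested.

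With a pseudocount of 0.1, 7 genes changed with Chd1-Ume6 in wild type, 90 in *rpd3* and 4 passed for the interaction of *ume6* and wild type. With a pseudocount of 5, which shrinks changes of weakly expressed genes, 23 genes changed with Chd1-Ume6 in *ume6*, 43 in *rrp6*, 2 in *isw2* and 18 in *rpd3*. No count moved by more than 1.5 times with either filter on low values.

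After quantile normalization 76 genes changed in *ume6*, 7 with Chd1-Ume6 in *ume6*, 14 for active against inactive, 9 with Chd1-Ume6 in *rrp6*, 25 in *rpd3*, 108 in the double deletion and 0 for the *rrp6* interaction. The early meiotic median was 0.12 in *rrp6* against wild type. Ribosomal protein medians reversed to 0.049 with Chd1-Ume6 in wild type, 0.088 in *rrp6*, 0.0067 in *isw2*, 0.064 in the double deletion and -0.24 for the *ume6* interaction. The histone median reversed to 0.18 with Chd1-Ume6 in wild type. After centring, 11 genes changed with Chd1-Ume6 in *rrp6*.

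With no table term 204 genes changed in *ume6*, 45 for active against inactive, 2 with Chd1-Ume6 in wild type, 59 in *rrp6*, 0 in *isw2* and 4 for the *ume6* interaction, the marker median with the inactive fusion was 0.24 and the stress median in *rrp6* 0.18. With the replicate block, which costs a degree of freedom, 4 genes changed with Chd1-Ume6 in *ume6*, 29 with Chd1-Ume6 in *rrp6*, 8 in *rrp6*, 0 in *isw2* and 140 in the double deletion. In the workbook alone, with fewer columns, these were 1 for Chd1-Ume6 in *ume6* and 2 for Chd1-Ume6 in *rrp6*. In the first table alone, which gave values without a test, the a-specific median with Chd1-Ume6 in *ume6* was -0.16. With missing values as 0, 3 genes changed with Chd1-Ume6 in wild type, 2 in *isw2*, 4 for the *ume6* interaction and 5 for the *rrp6* interaction. With the crossed replicate block 236 genes changed in *ume6*, 8 with Chd1-Ume6 in *ume6*, 3 with Chd1-Ume6 in wild type, 150 with Chd1-Ume6 in *rrp6*, 89 in *rpd3* and 46 for the *rrp6* interaction, and the stress median in *rrp6* was 0.14. The deviations of *rrp6* libraries numbered alike correlated at r = -0.337 across genes, so these data gave no sign that like numbers pair cultures. With 2 columns per group, libraries with unlike numbers correlate at the same size with a positive sign. Some structure is thus shared between unlike numbers, and its source was not tested. Choosing genes at 4-fold gave a median of -0.13, reversed from 0.09.

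Leaving out each library in turn, the count ran from 23 to 274 in *ume6*, 1 to 18 with Chd1-Ume6 in *ume6*, 1 to 5 with the inactive fusion, 4 to 35 for active against inactive, 0 to 2 with Chd1-Ume6 in wild type, 0 to 107 with Chd1-Ume6 in *rrp6*, 8 to 53 in *rrp6*, 0 to 1 in *isw2*, 28 to 68 in *rpd3*, 123 to 236 in the double deletion, 0 to 2 for the *ume6* interaction and 0 to 47 for the *rrp6* interaction. The early meiotic median ran from -0.34 to -0.064 for active against inactive and from 0.37 to 0.55 in *rrp6*. A group left with 1 column was assumed to vary like the others. Lists with a call, with or without the library, whose median reversed had these ranges. Marker genes with the inactive fusion ran from -0.074 to 0.13, the highest without *ume6* library 1. Stress genes with Chd1-Ume6 in *ume6* ran from -0.54 to 0.43 and were negative without *ume6* library 2 (-0.54) or fusion library 1 (-0.25). In *rrp6* against wild type they ran from -0.72 to 0.11, the highest without either library of Chd1-Ume6 in wild type, and for the *rrp6* interaction from -0.16, without library 1 of Chd1-Ume6 in wild type, to 1.43. Histone genes with the fusion in wild type ran from -0.30 to 0.0040, the highest without fusion library 1. With Chd1-Ume6 in *rrp6*, amino acid genes ran from -0.18 to 0.17 and were 0.13 without *rrp6* library 1. Ribosome biogenesis genes ran from -0.70 to 0.050, the highest without fusion library 2, and were 0.0031 without *rrp6* library 2. The a-specific genes ran from -0.32, without fusion library 2, to 0.036. Library 1 of a group in both tables is that of the first table. Depth is unknown, so how far it limits low values was not tested.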

Other observations

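The test of noncoding RNA on the same strand and the test of URS1 distance were set before their results were seen. The tests of facing small nucleolar or small nuclear RNA genes, of a low level and of the strength of repression, and the splits by motif, were chosen after.

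Several genes that rose in *rrp6* had a small nucleolar or small nuclear RNA gene as their neighbour. The first test counted called genes with a noncoding RNA gene of the same strand next to their 5' end, and found 1 of 15, against 196 of 5742 other genes (3.41%, two-sided Fisher's exact test p = 0.407). It decides little, because only 15 of the 20 called genes, or 75%, had an entry in R64. Of the 36 genes with a small nucleolar or small nuclear RNA gene in that place, 9 were at least 2-fold higher, against 340 of all 5757, but their median was 0.07, against 0.14. With any noncoding RNA gene there it was 17 of 197 and a median of 0.06, so neighbours on the same strand are left open. Inspection of the called genes then showed a different orientation, a small nucleolar or small nuclear RNA gene on the opposite strand that faces the gene from its 3' side. This held for *CMC4*, YJR129C, *LIN1*, *GLO4*, *MMS2* and *CUE5*, which is 6 of 15 against 24 of 5742, a count that has the same gap and was made on the genes that raised the idea. The 24 facing genes that were not called were therefore tested by themselves. Their median change was 0.41, at percentile 98.92 of random sets with a median of 0.14, and 8 of them were at least 2-fold higher, with *POP6* at 3.31 and *KTR2* at 2.04.

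A candidate explanation is that precursors of small nucleolar and small nuclear RNA, which Rrp6 trims, run on past their end in its absence and are counted in the gene that faces them, and the percentile of 98.92 is consistent with this. Reads by strand were not used here, and whether the counting used strand is not given, so it stays a hypothesis, and such a rise need not be a rise in the gene's own transcript. Called genes also had a low level in the *isw2* column, which the *rrp6* comparison does not use, with a median of 14.0 FPKM against 30.9 for random sets, at percentile 0.23. A low level leaves more room for a fold increase from added reads, so it may add to the rise of the 20 called genes, and it was not separated from the first explanation.

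In the promoters of the authors' motif genes, the URS1 core GGCGGC occurred within 800 bp upstream of the start codon in 178 of 222 genes (80.18%), against 684 of 5535 other genes (12.36%), with R64 as the sequence. Among motif genes at least 2-fold higher in *ume6* in the first table, the change with Chd1-Ume6 in the workbook rose with the distance of the core from the start codon (Spearman rho = 0.2683, Pearson r = 0.24, 70 genes, two-sided permutation p = 0.0254, and 0.0254 after adjustment over the 2 relations tested). The 46 genes with the core within 200 bp had a median of -0.60 and the 24 with it farther away -0.30. These values suggest that a core near the start codon may go with a larger loss of RNA, though genes are not independent replicates and the change comes from 1 library against 1.

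Motif genes that rose more in *ume6* in the first table also rose more with Chd1-Ume6 in *rrp6* in the workbook, a comparison that shares no library with the first (Spearman rho = 0.5151, Pearson r = 0.56, 227 genes, two-sided permutation p = 1e-05, the smallest that the permutations can give, and 2e-05 after adjustment). The 41 motif genes at least 4-fold higher in *ume6* had a median of 0.98 with the fusion in *rrp6*, and 38 of them were higher. The relation was not specific to motif genes, as genes without the motif gave rho = 0.2262 over 6014 genes, and the 70 of them at least 4-fold higher in *ume6* had a median of 0.78, with 54 higher. A loss of repression by Ume6 at its own targets may account for part of the rise, and a shift in growth state that raises genes of both kinds remains open.

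The a-factor gene *MFA1* was lower in both strains without Rpd3, and it passed in the double deletion only. It was at 77.8 FPKM in *rpd3* and 19.4 in the double deletion, against 360 in wild type and 218 in *isw2*. *PHO5* was at 1051 FPKM in *rpd3* and 1497 in the double deletion, against 356 in wild type, while the phosphate list it belongs to had a median of -0.58 in *rpd3* and -0.37 in the double deletion. These are single columns, and no explanation was tested for them.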
